A study of Mus with 6 samples.

How the data were processed

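The samples were 3 model and 3 AVE0991 samples of right substantia nigra pars compacta, grouped by their titles. Per the labels' protocols, total RNA was extracted with TRIzol, DNase-treated RNA went into the libraries, read quality was checked with FastQC 0.11.8 and reads were trimmed with fastp 0.19.5 where needed. Per the submitters' processing notes, STAR 2.7.7a, DESeq2 1.10.1 and the build mm9 were used; the counting program, the annotation and the strand setting are not given in the sources used here.

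The authors deposited a table of whole-number counts per NONCODE identifier and sample, and a table of FPKM for the same identifiers. Their deposited comparison by identifier gives a mean signal (counts divided by size factors), a log2 fold change and p-values; its mean signal equals the mean of the counts divided by median-of-ratios size factors, to a relative difference of at most 5e-15. The TPM table was not used here. The authors' deposited table by gene name gives, per the file headers, a mean signal per group, a log2 fold change, the statistic and degrees of freedom of a test per name, and its p-value. How names were assigned is not given in the sources used here.

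The main test for identifiers was edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, R 4.3.3) on the deposited counts, with Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. The design had planned the same fit for lncRNAs. Since no file pairs names with identifiers, the counts behind the named table were recovered instead, a step chosen after seeing the data. Each group mean is a mean of 3 counts, each divided by a library factor, and the test statistic with its degrees of freedom gives both variances. Of 2247 names with a value, 2240 (99.69%) had exactly 1 set of whole counts that returned the mean (relative tolerance 1e-09) and the variance; 2 had several sets and 5 lay above the level solved. Names with several sets or above that level were not tested. They include the abundant lncRNAs Malat1, Meg3, Norad and Lncpint. A further 35 names were 0 throughout. The same edgeR test then ran on the recovered counts, adjusted over the named RNAs alone. The recovered libraries, called a, b and c in each group, carry no replicate numbers and were not matched to them. Their normalized counts are counts divided by the recovered library factors, which ran from 0.921 to 1.18.

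The named genes followed a rule fixed before the data were examined: Hotairm1, Mir223, Mas1 and a further gene that is not reported here; the 10 largest changes per direction among those past the threshold with a mean log2 CPM of at least 1, no overlap between groups and a symbol that is not a clone name; the 5 smallest p per direction; and up to 4 members of each described list. The same rule gave the 4 identifiers, limited to 2 per direction. Other members of groups made by name were chosen after their values were seen. Of the 2282 names, 2270 matched a RefSeq symbol (GRCm38.p6), used for class, neighbours and the span of the gene; no coordinates are given because the builds differ.

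Groups of names were tested with Fisher's exact test, camera and fry (limma 3.58.1), adjusted over 10 groups. Alternatives were DESeq2 size factors, library totals, DESeq2 1.42.0, limma-voom, other filters, robust fitting, each library left out, the replicate number as a block, and limma on log2(FPKM + 1) and log2(FPKM + 0.1).

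The steps were tested on simulated data. Identifiers were simulated once (51507 tested), with 95 changed 2-fold and 97 changed by 2 on the log2 scale. Of these, 20% and 69.1% were called, and 11.3% of calls were unchanged identifiers, above the nominal 5%. For named RNAs, also simulated once (1837 tested, 100 and 96 changed), the shares were 48% and 85.4%, with 4.41% of calls unchanged. The changed identifiers were a far smaller share than was called in the data, so their rates need not hold there. The recovery step gave 1 set for 99.78% of simulated names, and all 2231 sets were the simulated counts.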

Results

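RNA was measured in the right substantia nigra pars compacta, the midbrain region that holds the dopaminergic neurons lost in Parkinson's disease, of mice overexpressing human α-synuclein with the A53T substitution. The comparison was between 2 groups of 3 samples each. The model group received 0.9% saline and the other group received AVE0991 at 10 mg/kg, both by daily intraperitoneal injection for 30 days. AVE0991 is a non-peptide agonist of Mas, the receptor of angiotensin-(1-7). The series title links the drug to the long non-coding RNA (lncRNA) HOTAIRM1 and to miR-223-3p. The count table by identifier held 87858 NONCODE gene identifiers, and its libraries held 47630902, 43991913 and 52029003 counts in the model group and 42379095, 42206840 and 37036986 in the AVE0991 group. A separate table by gene name held 2282 names, mostly lncRNAs, with 1801 that RefSeq lists as lncRNA, 256 as miRNA, 118 as transcribed pseudogenes and 56 as protein-coding. No file paired identifiers with names. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

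The question was which non-coding RNAs differ between treated and untreated mice of this genotype. Among named RNAs, Hotairm1, the lncRNA of the HoxA cluster in the study's title, fell. Its normalized count was 78.8 ± 7.74 (SD, n = 3) in the model group and 21.5 ± 11.2 (SD, n = 3) with AVE0991, a log2 fold change of -1.82 ± 0.42 (SE). The call (adjusted p = 0.0235, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) was lost when AVE0991 library b or c, or model library a or b, was left out (adjusted p = 0.0795, 0.0618, 0.0787 and 0.0911 by the same edgeR test). For antisense RNAs in general, reads from the RNA and from a gene it overlaps cannot be told apart without strand information. Mas1 and Mir223 were not analysed here.

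In all, 298 of 1867 named RNAs changed, 143 higher and 155 lower with AVE0991, in an edgeR quasi-likelihood test on whole counts recovered from the authors' deposited named table. Of these, 184 changed by at least 2-fold. The tested names include 48 that RefSeq lists as protein-coding, 7 of which changed. The authors' deposited table gave an unadjusted p under 0.05 for 423 names, and none of its 2247 p-values passed after Benjamini-Hochberg adjustment here (smallest adjusted value 0.0811). With 1 library left out, 142, 153 and 149 RNAs changed without AVE0991 library a, b or c, and 112, 93 and 417 without model library a, b or c.

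Among RNAs whose symbols are not clone names, the largest rises included RNAs of developmental loci. Dlx6os1, the antisense partner of the forebrain homeobox gene Dlx6, rose from 2705 ± 1417 to 17283 ± 2805 normalized counts (SD, n = 3 each), a log2 fold change of 2.73 ± 0.35 (SE). Sfta3-ps, which neighbours Nkx2-1 in RefSeq, rose by 3.04 ± 0.32 on the log2 scale, from 44.2 to 353 normalized counts. Sox1ot, which overlaps Sox1, rose by 1.44 ± 0.21. With clone names left out, the rest of the 10 largest rises were Ptprv, Art2a, Grip1os1, Pldi, Trerf1 (protein-coding in RefSeq), Mir135a-1 and Rps4l, whose log2 fold changes ran from 1.17 for Rps4l to 2.16 for Ptprv. The calls of Art2a, Pldi and Mir135a-1 were each lost in 5 of the 6 fits with a library left out. Those of Trerf1, Grip1os1 and Rps4l were lost in 3, 2 and 2. By smallest p, with clone names kept, the risers also included 1700096J18Rik (log2 fold change 2.01), 3110009F21Rik (2.91), Gm6416 (2.75) and AI197445 (fold change 2.83).

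With clone names again left out, the largest falls included RNAs next to the homeobox genes Lhx1, Pax6 and Dlx4. Lhx1os, beside Lhx1, had the smallest p of all named RNAs and fell from 1027 ± 131 to 143 ± 8.52 normalized counts (SD, n = 3 each), a log2 fold change of -2.79 ± 0.18 (SE). Paupar, beside Pax6, had a log2 fold change of -2.41 ± 0.20, from 465 to 84.3 normalized counts. Dlx4os, which overlaps Dlx4, had one of -2.17 ± 0.40. Snhg8, a host gene of a small nucleolar RNA, fell from 45.1 to 6.52 normalized counts. Lincmd1 had 3 recovered counts with AVE0991 and 174 in the model group, a ratio of model to AVE0991 of 49.7 after library scaling (95% exact Poisson interval 16.7 to 243). Far1os had 2 and 67 counts, a ratio of 28.7 (interval 7.64 to 242). These intervals cover counting error only, and the AVE0991 counts of both RNAs all lie in library b. Without it the AVE0991 group had no counts, so the fitted log2 fold changes of -8.74 and -7.37 have no firm size. The call of Far1os was lost without library b (adjusted p = 0.0527, edgeR). It was lost in 6 of 14 alternatives in all, 5 of them with a library left out (adjusted p up to 0.140, edgeR). By smallest p, 8430422H06Rik also fell, with a log2 fold change of -2.94.

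**Figure D1:**
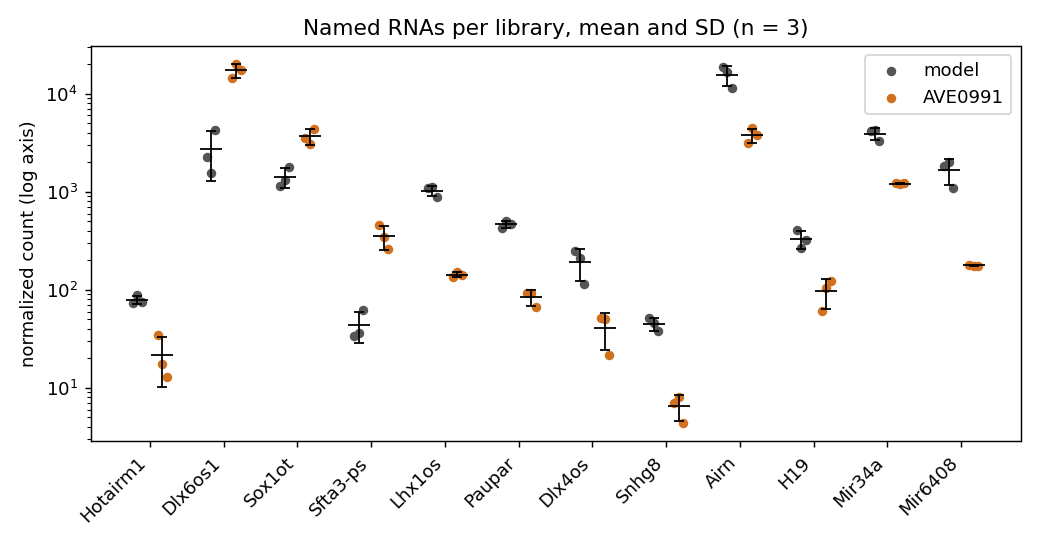
Normalized counts per library (log axis) of 12 named RNAs in the model (grey) and AVE0991 (orange) groups, with bars for the mean and SD of 3 libraries. Dlx6os1, Sox1ot and Sfta3-ps lie higher with AVE0991 and the other 9 lie lower, with no overlap between groups.

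Named RNAs were also grouped by locus or class. The groups were made after names and values had been seen, so their tests are not independent evidence. Of 21 tested RNAs named after developmental transcription factors outside the Hox clusters, 4 rose, 5 fell and 12 did not pass; Sfta3-ps is not among them, by its name. The risers were Dlx6os1, Sox1ot, Zeb2os and Emx2os, and those that fell were Lhx1os, Paupar, Dlx4os, Otx2os1 and Prox1os. This was 42.9% changed against 15.7% of other names (Fisher's exact test, two-sided, adjusted p = 0.0296 over 10 groups). That test takes RNAs from the same libraries as independent, so it does not measure the spread between samples. Fry regardless of direction gave an adjusted p of 0.000757, but at most 0.0241 in every group. Tests for a shared direction gave 0.763 and 0.732 (camera, preset and estimated correlation) and 0.0936 (fry) for these 21 RNAs. Leaving out AVE0991 library b, or model library a or b, left 5 changed in each case, and 7, 6 and 10 changed without AVE0991 library a or c or model library c; the calls of Zeb2os, Emx2os, Otx2os1 and Prox1os were lost in each of the fits that left 5. Of 7 RNAs of the Hox clusters, 1 fell (Hotairm1) and 6 did not pass. Hoxaas2 and Halr1 had log2 fold changes of -2.59 ± 0.99 and -1.58 ± 0.79 (SE), which ran from -5.08 to -2.03 and from -2.49 to -1.14 over the alternatives; Hoxaas2 had 9.42 ± 13.7 normalized counts with AVE0991 (SD, n = 3) and passed in 2 of 14 alternatives (DESeq2, and edgeR without AVE0991 library a). In the main test, Hotair and Evx1os had log2 fold changes of 0.58 ± 0.56 and 0.25 ± 0.18.

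Of 9 tested RNAs of imprinted loci, 3 fell and 6 did not pass. Airn, the antisense RNA of the Igf2r imprinted cluster, fell from 15550 to 3776 normalized counts (log2 fold change -1.99 ± 0.21, SE). In RefSeq's GRCm38.p6 annotation Airn overlaps Igf2r and Mas1, the gene of the receptor AVE0991 acts on. H19 and Igf2os, which lie at the Igf2 locus, had log2 fold changes of -1.72 ± 0.31 and -1.55 ± 0.30. Of 14 host genes of small nucleolar RNAs, 1 fell (Snhg8) and 13 did not pass; Gas5, for one, had a log2 fold change of 0.22 ± 0.14.

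Among 221 tested miRNA loci, 35 fell, 1 rose (Mir135a-1) and 185 did not pass. Mir34a, a miRNA gene induced by p53, fell from 3905 ± 542 to 1211 ± 14.7 normalized counts (SD, n = 3 each). Mir6408, Mir6400, Mir3107 and Mir6354 had log2 fold changes of -3.16, -3.08, -2.24 and -3.45. The median log2 fold change of the loci was -0.37. With the trend of fold change on annotated gene span taken out of each library, an alternative chosen after seeing the data, 10 loci were lower, 7 were higher and the median was 0.06. As a set they were lower than other names in camera with a preset correlation (adjusted p = 7.6e-09 over 10 groups), but not with an estimated correlation (camera, adjusted p = 0.501). These counts come from total RNA libraries at loci named after miRNAs and do not measure mature miRNAs. Without AVE0991 library a, b or c, 14, 20 and 19 loci changed, and without model library a or b, 14 and 12, all lower; without model library c, 42 were lower and 1 higher.

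Of 16 immune and interferon RNAs tested, Gbp11 and H2-K2 fell, with log2 fold changes of -0.76 ± 0.19 and -0.87 ± 0.25 (SE), and 14 did not pass. RefSeq lists both Gbp11 and H2-K2 as transcribed pseudogenes. The H2-K2 call was lost in 8 of 14 alternatives, 4 of them with a library left out (adjusted p from 0.0220 to 0.146 over all 14), and the Gbp11 call in 5 of the 6 fits with a library left out (adjusted p up to 0.113). Mx1, an interferon-induced gene that RefSeq lists as a transcribed pseudogene, did not differ beyond the spread. It had 52.5 ± 39.4 normalized counts with AVE0991 and 30.0 ± 24.1 in the model group (SD, n = 3 each). Of the 39 gene lists fixed before the data were examined, 2 had any member in the named table and none had 3, so the planned list tests, cell type markers included, were not run.

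**Figure D2:**
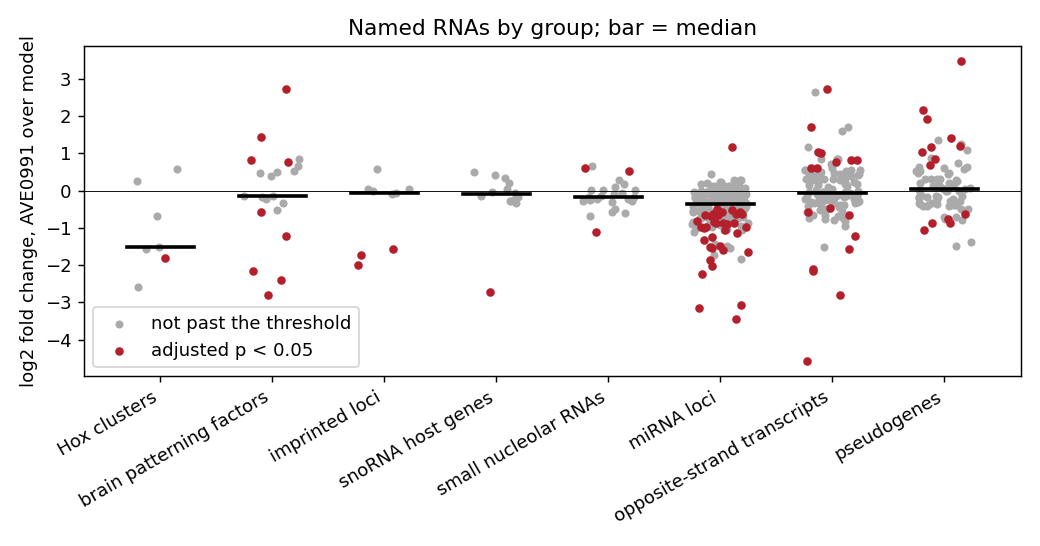
Log2 fold change, AVE0991 over model, of each tested RNA in 8 groups of names. Red points passed an adjusted p of 0.05, grey points did not, and bars give each group's median, which was -0.37 for miRNA loci and -0.16 for small nucleolar RNAs.

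Across identifiers, 10363 of 53206 tested changed, 5388 higher and 4975 lower with AVE0991, and 6432 of them changed by at least 2-fold. Among those with the largest changes, NONMMUG058670.1 rose from 0.510 ± 0.263 to 10.6 ± 2.52 CPM (SD, n = 3 each) and NONMMUG058657.1 from 1.81 ± 1.27 to 22.3 ± 3.71. NONMMUG032923.2 fell from 50.9 ± 14.6 to 0.397 ± 0.589 and NONMMUG074498.1 from 36.9 ± 9.26 to 0.333 ± 0.412. The share of identifiers that changed was 5.59% among the 13302 least abundant and 31.0% among the 13302 most abundant. The authors' deposited table marked 5021 identifiers up and 4237 down, by an unadjusted p under 0.05 and a change of over 2-fold, and 11474 of its adjusted p-values were under 0.05. Without model replicate 1, 2 or 3 the count was 5495, 5991 or 13534, and without AVE0991 replicate 1, 2 or 3 it was 7098, 7383 or 6970.

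The first principal component held 53.1% of the variance and separated the groups. Model replicate 3 lay between them. Its Spearman correlation with the AVE0991 libraries, across identifiers, ran from 0.928 to 0.940, against 0.887 to 0.907 for the other model libraries. In that library 2 identifiers held 11.6% of the counts, against 1.15% and 1.58% in the other model libraries and 1.46% to 5.28% with AVE0991.

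**Figure D3:**
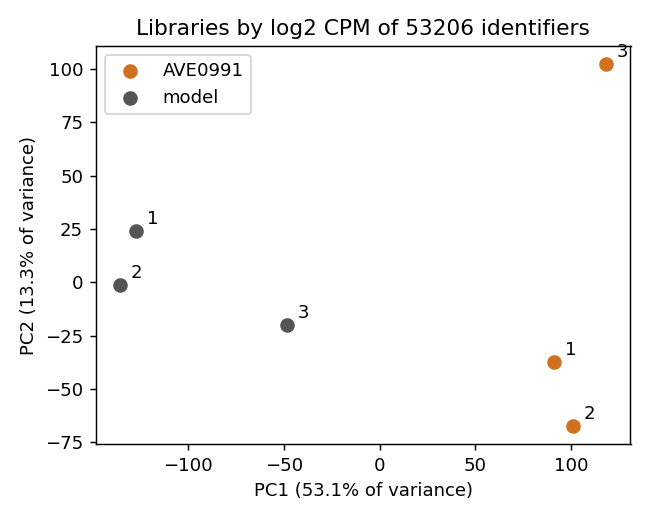
Principal components 1 and 2 of log2 CPM, with 1 point per library, labelled by replicate number. The groups lie apart on component 1, which held 53.1% of the variance, and model replicate 3 lies nearest to the AVE0991 libraries.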

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

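The recovery of named counts, the authors' library factors, the authors' adjusted p, the 4-library fit and the removal of 2 identifiers were chosen after seeing the data. The number of identifiers changed stayed within 1.5 times of 10363 under the other alternatives run. The exceptions were a 2-fold minimum (6432) and leaving out model replicate 1 or 2. Over all fits with a library left out the number ran from 5495 to 13534. Without model replicate 1 or 2 it was 5495 or 5991, with 5366 and 5861 of these also in the main list, in the same direction. Fewer libraries enter those fits. The 4 libraries other than AVE0991 replicate 1 and model replicate 3 gave 11234. For named RNAs, scaling, filter and test choices gave 280 to 404, of which 276 to 298 were shared with the 298. A 2-fold minimum gave 184, leaving out a library gave 93 to 417, and the authors' adjusted p gave 0. That test estimates the spread of each name from 3 values per group alone. It had 423 names at an unadjusted p under 0.05, 417 of them among the names tested here, where edgeR had 577. After adjustment, DESeq2 called 404 and limma-voom 334. Of 43 RNAs and identifiers named as changed, 24 stayed past the threshold in every alternative checked for them, and none changed sign. These were 14 fits per RNA and 16 per identifier. The authors' adjusted p, which no name passed, and the fit with the span trend taken out were not among them. The other 19 were lost in at least 1 fit without a library, where fewer samples enter: Hotairm1, Art2a, Grip1os1, Pldi, Trerf1, Mir135a-1, Rps4l, Far1os, Snhg8, Igf2os, Emx2os, Zeb2os, Otx2os1, Prox1os, Snora24, Snord89, Snora3, Gbp11 and H2-K2. Of these, Far1os, Prox1os, Snora24, Snord89 and H2-K2 were also lost in at least 1 other alternative; the cause was not tested. Of the 13302 least abundant identifiers 5.59% changed; whether depth limits calls there was not tested.

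With the replicate number as a block, 10217 identifiers changed, 9479 of them among the 10363. Deviations from the group means correlated at 0.01, 0.06 and 0.02 between samples of the same number. Between samples of different numbers the correlations ran from -0.05 to 0.02. All lie near 0, so the numbers do not show paired samples. For named RNAs no block and no FPKM alternative was run, since the recovered libraries carry no number and the FPKM table carries no names. The planned gene list tests were not run.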

Other observations

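All tests in this part were chosen after the results were seen. Among 80 transcribed pseudogenes tested, 9 rose and 5 fell, and those that fell include Gbp11 and H2-K2, already counted among the immune RNAs. Of 26 small nucleolar RNAs, Snora24 and Snord89 rose and Snora3 fell, with log2 fold changes of 0.54, 0.60 and -1.10. Their calls were lost in 6, 8 and 4 of 14 alternatives. Among 5 RNAs of the X inactivation centre and Firre, none passed the edgeR test; at an unadjusted p under 0.05, Ftx had a log2 fold change of 1.63 ± 0.55 (SE).

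The number of changes was large for 3 libraries against 3. Of the 10 splits of the 6 libraries, 1 (the real one) gave as many changed identifiers (10363, highest other 2), and 1 gave as many named RNAs (298, highest other 1); 10 splits are too few for a share under 0.05. Removing the 2 identifiers whose share varied most left 10409. TMM scaling already adjusts for such shares (factor 0.851 for model replicate 3), so the removal could hardly move the count and does not decide. Over named RNAs the log2 fold change rose with annotated gene span (Spearman's rho 0.23 across 1857 names, which are not independent replicates). With that trend taken out of each library, 256 of 1857 changed against 296 before, 232 of them shared. The trend fitted to the fold changes ran only from -0.47 to 0.33, and 236 of 297 changed names exceeded its whole range. A trend of that size does not account for most calls, so its removal could hardly move the count. This criterion was added after rho was seen. The span is that of the RefSeq gene, and the length of the counted feature was not tested. Differences in dissection, handling or batch, for which the labels give no term, cannot be separated from the treatment here.

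RNAs at patterning loci moved both ways, and one hypothesis is a different share of neighbouring brain regions in the dissected tissue. Lists of forebrain and Hox-cluster lncRNAs, written after their values were seen, had 3 members past the threshold in the direction this needs: Dlx6os1 and Emx2os higher and Hotairm1 lower. The lists left out Evx1os (log2 fold change 0.25), one of the 7 Hox-cluster RNAs tested, patterning RNAs that fell, such as Otx2os1 (-1.23) and Paupar (-2.41), and Sfta3-ps, beside Nkx2-1, which rose (3.04), so this count was set in part by the choice of members and does not decide. Of the listed Hox RNAs, Hotair had a log2 fold change of 0.58 ± 0.56 (SE), and the summed normalized counts were 249, 73.5 and 60.8 in AVE0991 libraries a, b and c and 215, 369 and 249 in model libraries a, b and c. The forebrain sums, 15152 to 20588 with AVE0991 and 1917 to 4756 in the model group, did not overlap, but Dlx6os1 makes up most of them. The samples differ by treatment and by any dissection difference at once, so the explanations cannot be told apart, and the fall of Hotairm1 may reflect either.

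The median below 0 of the miRNA loci, of which 35 of 221 fell past the threshold, may reflect how short RNAs were recovered. Small nucleolar RNAs, also short, had a median log2 fold change of -0.16 against -0.37 (permutation test over loci, two-sided, p = 0.0601), which leaves this open. The length of the RNAs counted at the miRNA loci is not known. The comparison therefore need not bear on short RNAs. With the span trend taken out, 10 loci were lower and 7 higher with a median of 0.06, but miRNA loci make up much of the short end from which that trend was estimated, so this does not decide. Reads from protein-coding host genes would leave loci outside such genes near 0, and their median was -0.40 (81 loci, 95% bootstrap interval -0.53 to -0.31). The 56 loci that overlap no other RefSeq gene, coding or non-coding, had a median of -0.39 (interval -0.53 to -0.23). By their selection these loci overlap no other RefSeq gene, but the annotation used for counting is not given. If the counted features match the RefSeq spans, host reads are not needed for a median below 0 at these loci. Otherwise host reads stay open for them too. For the 165 loci inside another gene (median -0.34; permutation test against the loci outside, two-sided, p = 0.69) host reads stay open, and reads from unannotated transcripts were not tested. The bootstrap intervals and permutation tests here resample loci, which all share the same libraries, so they do not measure the spread between samples. A treatment effect on the miRNA loci stays open and was not tested apart from these explanations.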
